A study of Mus musculus with 57 samples.

How the data were processed

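RNA from 57 individual mouse embryos was profiled by paired-end RNA sequencing in 3 lines, each carrying an allele of Taf5, Taf12 or Taf13. Embryos were collected as blastocysts at embryonic day 3.5 (E3.5), as blastocyst outgrowths (OG, cultured for 72 h in serum-containing medium from E3.5), or at E6.5. Genotypes are given per the labels as WT, HET and MUT. The samples formed 14 groups in 5 combinations of line and stage. The labels do not describe the alleles and do not say whether embryos came from separate litters, so p-values measure the spread between these samples.

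Per the submitters' processing notes, Trimmomatic 0.39, FastQC 0.11.9, STAR 2.7.6a, R 4.2.1 and DESeq2 1.36.0 were used with the mouse genome build GRCm39. The part each tool played, the program that counted reads per gene and its strand setting are not given in the sources used here. The authors deposited a table of FPKM (fragments per kilobase and M reads, M for mega) for 56557 genes in every sample, of which 37343 were above 0 in at least 1 library. A second deposited table holds the authors' comparison of mutants with WT (Taf5) or with WT and HET together (Taf12 and Taf13), as the mean normalized count, the log2 fold change with its standard error, and the unadjusted and adjusted p-value. The ratio of each gene's mean FPKM to the authors' mean normalized count was constant across lines and stages, up to 1 factor, for 97.0 to 99.9% of genes. The authors therefore normalized each of the 5 line and stage sets separately, and levels set side by side across lines or stages come from separately normalized tables.

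Read numbers were recovered by dividing each FPKM by the FPKM that 1 read gave in that gene and library. Of the values up to 500 reads, 99.95% were whole within 0.05 reads over all libraries and 99.78% in the lowest library. Recovered reads summed to 9.73 to 12.07 M per library in Taf5 E3.5, 7.81 to 10.17 M in Taf12 E3.5, 4.57 to 12.56 M in Taf12 OG, 8.61 to 10.29 M in Taf13 E3.5 and 18.39 to 21.53 M in Taf13 E6.5. The FPKM values imply lengths shorter than those of the transcripts for many genes, such as 69.4 bases for Actb, 65.2 for Plat, 212 for Pou5f1 and 10.4 for Slain1, against 2100 for Taf12 and 2220 for Taf13. The median implied length of tested genes was 892 bases and the 1st decile was 120. FPKM levels were therefore compared within a gene and not between genes. They are relative to the other transcripts of a library, so rises and falls are not changes in amount per embryo. A single read exceeded FPKM 1 in 3.74% of tested genes in Taf5 E3.5, 8.2% in Taf12 E3.5, 6.74% in Taf12 OG, 6.56% in Taf13 E3.5 and 0.201% in Taf13 E6.5.

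Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with data.table (1.17.8). Genes were tested when at FPKM 1 or more in at least as many libraries as the smallest group held. The libraries of 1 line and stage shared a fit with a mean-variance trend and robust variance moderation. MUT and HET were each compared with the WT of the same line and stage. Differences between stages, and between lines at E3.5, were tested as contrasts of effects, each effect taken against its own WT. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit, and adjusted p without another source is limma's over all genes tested. FPKM levels are means ± SD over the libraries of a group, and folds without a log2 label are ratios of group means. Where every library of a group was at 0, a lower bound was set at 3 reads per library. Groups with 1 to 3 reads in all are given with a fold from summed reads and its 95% counting interval. Intervals and floors cover counting error only.

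Lists of genes for transcription machinery, stress and metabolic pathways, embryonic and extraembryonic cell types, maternal tissue and embryo sex were fixed in advance. So were the comparisons, thresholds, alternative settings and the rule for named genes. Lists of at least 3 tested genes were tested with camera at a preset correlation between genes of 0.01. Lists pass by this test, also without a library. They were tested again with an estimated correlation and with fry, Benjamini-Hochberg adjusted over a comparison's lists. The naming rule took the 3 targeted genes and up to 8 called genes per direction by fold for MUT (4 for HET and for contrasts of effects). Those genes had libraries that did not overlap between MUT or HET and WT (not asked of contrasts of effects), FPKM 5 or more in the higher group, and a symbol that is not a predicted gene, clone or pseudogene name. From each list that passed or had 3 or more called members, up to 4 members with the smallest p were taken. Where no gene was called, the 3 with the smallest p were taken. Which list members the text names was chosen after seeing values.

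Simulated data had the same group sizes and depths, with a shared dispersion per line and stage. The test called 2 to 37% of genes changed 2-fold and 82 to 99% of those changed 4-fold, 0 in the wrong direction. Of 88 to 145 calls per comparison, 3 to 12 were false. The rates may not hold for genes of few reads. Over 105 pairs within groups the smallest chi-square per gene was 16.8, so no libraries were duplicates up to counting noise. The alternative settings fixed in advance covered the pseudocount, the expression filter, scaling between libraries, the variance model, library weights, a fold limit, a count test (voom on recovered reads), fits of only the groups compared, WT and HET together as control, the replicate number as a block and leaving out each replicate. Chosen after seeing the data were an embryo-sex covariate, leaving out the X and Y chromosomes, a filter on recovered reads, and leaving out 2 E6.5 libraries with high decidual transcripts.

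Gene identifiers and symbols are those of the authors' table. The annotation at hand was of the older build GRCm38, in which 51942 of the 56557 identifiers were found. It was used for chromosome names only, and no coordinates are given. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Sequence reads were not used here. Gene families that share reads (cathepsins, histones, ribosomal proteins, Stfa1, Ceacam15) and antisense or overlapping transcripts (Rbfaos, Tincr) have uncertain levels, because the counting rules and strand setting are not stated.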

Results

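Single mouse embryos of 3 lines were profiled by RNA sequencing to ask what early development requires of 3 factors that bind with the TATA-binding protein. Taf5 and Taf13 encode subunits of TFIID, the general transcription factor that recognises core promoters, and Taf12 encodes a subunit that TFIID shares with the coactivator SAGA. The Taf5 line gave E3.5 blastocysts (WT n = 3, MUT n = 4). The Taf12 line gave blastocysts (WT n = 5, HET n = 5, MUT n = 3) and outgrowths, which are blastocysts left to attach and spread in culture (WT n = 4, HET n = 3, MUT n = 4). The Taf13 line gave blastocysts (WT n = 4, HET n = 4, MUT n = 3) and E6.5 embryos (WT n = 4, HET n = 9, MUT n = 2). Depth ran from 4.57 M recovered reads in the outgrowth MUT 3 library to 21.53 M in the E6.5 HET 9 library. Mitochondrially encoded transcripts took 1.76 ± 0.322% of reads in outgrowth MUT against 1.11 ± 0.161% in WT. In E6.5 MUT they took 1.12 and 0.38% in the 2 libraries, against 0.31 ± 0.177% in WT.

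The transcript of the targeted gene was absent in 1 of the 3 lines. Taf5 had 0 reads in all 4 Taf5 MUT libraries and 35.7 ± 20.1 FPKM (SD, n = 3) in WT, at least 32.7-fold lower (log2 fold change −4.99, SE 0.53, adjusted p = 0.0316). In libraries labelled Taf12 MUT, Taf12 was at 62.2 ± 5.6 FPKM against 44.6 ± 6.64 in WT blastocysts (adjusted p = 0.229). In outgrowths it was 2.28-fold higher, at 52.9 ± 0.82 against 23.2 ± 3.7 (log2 1.17, SE 0.17, adjusted p = 0.000489). In libraries labelled Taf13 MUT, Taf13 was at 24.4 ± 10 against 37.5 ± 8.64 at E3.5 (adjusted p = 0.552) and at 30.7 ± 5.05 against 32.4 ± 10.3 at E6.5 (adjusted p = 0.956). Taf12 in Taf12 HET was at 41.7 ± 6.15 FPKM at E3.5 and 21.1 ± 4.73 in outgrowths, and Taf13 in Taf13 HET at 26.7 ± 3.4 at E3.5 and 27.3 ± 8.99 at E6.5, none called against WT. The labels of the Taf12 and Taf13 mutants were therefore not borne out by the level of the targeted transcript, and these genotypes are taken from the labels.

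Taf13 and Taf5 were higher in Taf12 MUT outgrowths. Taf13 rose 3.17-fold in Taf12 MUT blastocysts, to 102 ± 19.9 from 32 ± 7.9 FPKM (log2 1.65, SE 0.25, adjusted p = 0.0111), and 4.28-fold in Taf12 MUT outgrowths, to 120 ± 18 from 28.1 ± 4.87 (log2 2.06, SE 0.16, adjusted p = 1.48e-05). Taf5 rose 3.09-fold in Taf12 MUT outgrowths (76.6 ± 14.8 against 24.8 ± 14.4 FPKM, adjusted p = 0.00542). In Taf12 MUT blastocysts Taf5 was at 77.7 ± 13.9 against 17.5 ± 12.2 (log2 2.43, adjusted p = 0.0895). In Taf5 MUT blastocysts Taf12 was at 91.7 ± 7.3 against 43.4 ± 12.2 (adjusted p = 0.369) and Taf13 at 66.9 ± 7.64 against 35.9 ± 14.2 (adjusted p = 0.486). In Taf13 MUT, Taf5 was at 54.5 ± 31.7 against 31.7 ± 15.9 and Taf12 at 53.5 ± 7.21 against 45.3 ± 7.86 at E3.5. At E6.5 Taf5 was at 26.9 ± 14.7 against 24.1 ± 7.64 and Taf12 at 35.9 ± 0.93 against 33.5 ± 9.25, none of them called.

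**Figure D1:**
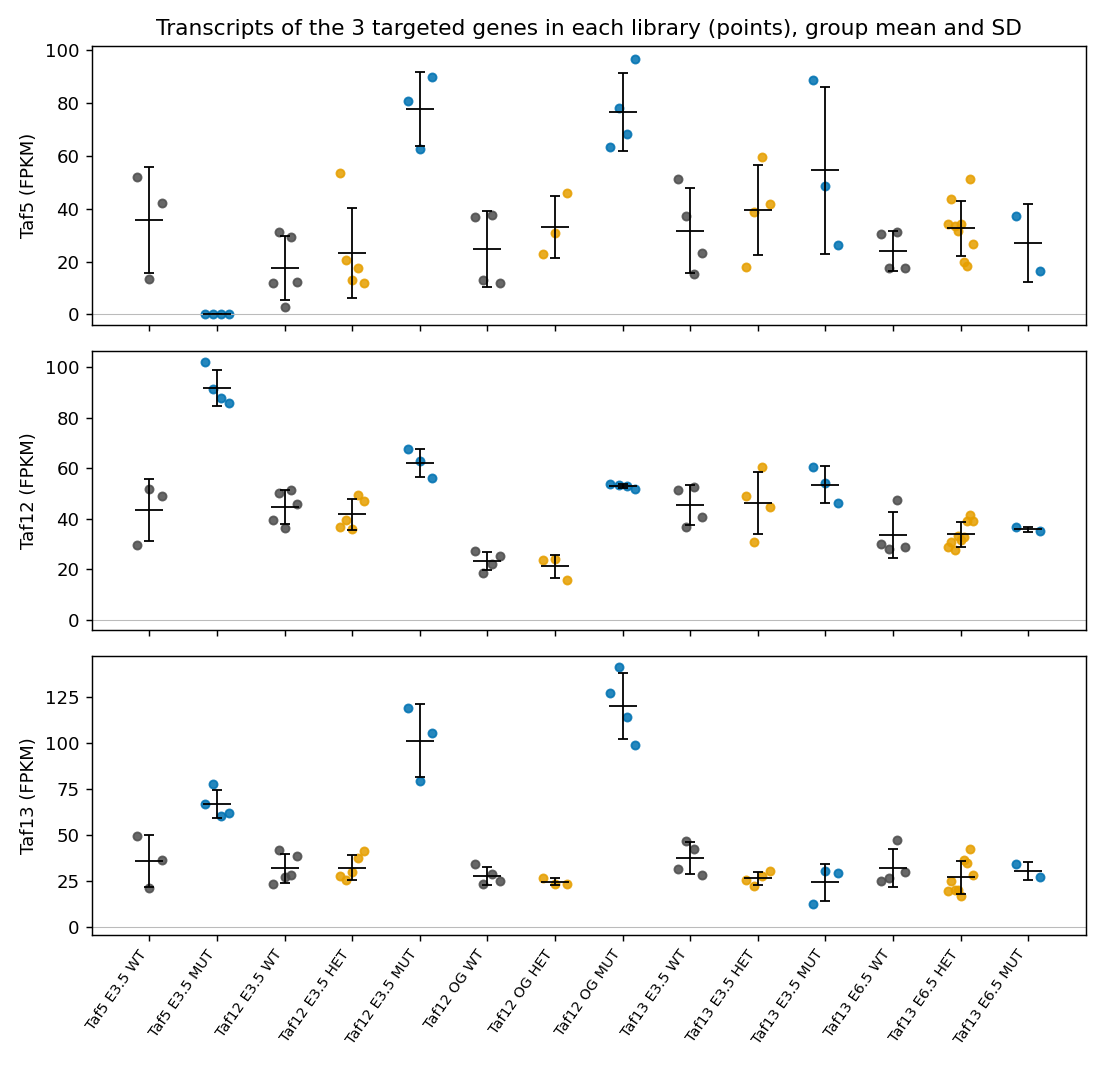
FPKM of Taf5, Taf12 and Taf13 in each library (points) of the 14 groups, with group means and SD. Taf5 is at 0 in all 4 Taf5 MUT libraries, and Taf13 is highest in Taf12 MUT outgrowths, at 120 ± 18.

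Whether blastocysts without reads of Taf5 had altered expression was tested at E3.5. Besides Taf5 itself, 7 genes fell and 4 rose. Zfp438, a zinc finger gene, and Tincr, an RNA known from epidermal differentiation, had 0 reads in MUT against 145 ± 40.3 and 66.2 ± 7.05 FPKM in WT, at least 32.8-fold and 22.7-fold lower (adjusted p = 0.000846 for each). Prkch, a protein kinase C gene, fell at least 28.4-fold, Magef1 at least 11.1-fold and Lrrc70 at least 8.5-fold, each with 0 reads in MUT. Bpgm, the bisphosphoglycerate mutase, had 2 reads in MUT (142-fold lower, interval 38.7 to 1180), as had Lrrc75b (78.2-fold lower, interval 21.2 to 652), all in MUT 4 (at least 23-fold and 12.7-fold lower without it). Lrrc56 was at 76.8 ± 26 FPKM in MUT and had 0 reads in WT, at least 33.4-fold higher (adjusted p = 0.000846). Evl, an actin regulator, rose at least 12.4-fold and Zfp959 at least 31.5-fold. Pcif1, the cap methyltransferase, rose 8.35-fold, to 33.6 ± 1.12 from 4.02 ± 0.443 FPKM (log2 2.79, SE 0.25, adjusted p = 0.0226).

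As groups, p53 targets stood lower in Taf5 MUT (24 genes, median log2 fold change −0.65, adjusted p = 0.000653), with adjusted p = 0.412 with an estimated correlation. None of the 24 was called over all genes and 3 fell when adjusted over the list alone. Plk2 was at 1.24 ± 1.44 against 29.2 ± 24.9 FPKM, Zmat3 at 0.121 ± 0.243 against 3.97 ± 2.98 and Btg2 at 2.14 ± 0.236 against 13.1 ± 11.3 (adjusted p = 0.303 to 0.486). Immediate early genes (11 genes, median −0.76, adjusted p = 0.0116) included Myc, at 107 ± 42.4 against 288 ± 119 FPKM. Extraembryonic ectoderm genes (14 genes, median −0.55, adjusted p = 0.00655) included Pcsk6, at 53.2 ± 6.38 against 124 ± 25.1, and Eomes, at 168 ± 78.6 against 331 ± 99.6, with 1 member lower when adjusted over the list alone. Genes of RNA polymerase II and its general factors stood higher (32 genes, median 0.14, adjusted p = 0.00749), with Polr2a at 430 ± 45.5 against 232 ± 44.5, and 1 member was higher adjusted over the list alone. For these 3 groups adjusted p = 0.412 with an estimated correlation. Cytosolic ribosomal protein genes stood lower (79 genes, median −0.14, adjusted p = 0.000848, adjusted p = 0.612 with an estimated correlation), with Fau at 3350 ± 251 against 4660 ± 317 and Rplp2 at 3070 ± 247 against 4200 ± 106. TFIID subunits did not pass (14 genes, adjusted p = 0.233). Their median was 0.12 and the test upward while the mean was −0.08, since Taf5 itself was among them.

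Of 10843 genes tested in the Taf5 line, 12 were called, 882 were under an unadjusted p of 0.05, and the count test voom called 0. The authors' table listed 220 genes, 104 higher and 116 lower. The count was 3 without MUT 1, 5 without MUT 2, 4 without MUT 3 and 6 without MUT 4, and the call of Taf5 held only without WT 2 (adjusted p = 0.0332). It was lost without WT 1 (0.0761), WT 3 (0.114), MUT 1 (0.123), MUT 2 (0.073), MUT 3 (0.0964) or MUT 4 (0.0773), though Taf5 had 0 reads in every MUT library. Calls of Lrrc56, Zfp438 and Tincr held without any library, while Evl, Zfp959, Prkch and Lrrc75b were lost without any 1 of the 7. Bpgm held without MUT 4, Lrrc70 and Magef1 without WT 2, and Pcif1 without WT 1, with a highest adjusted p of 0.147 among the others (Magef1 without WT 1). At preset correlation p53 targets passed without each library. Immediate early genes did not without WT 1 (0.159), MUT 1 (0.0548) or MUT 4 (0.141), nor extraembryonic ectoderm without WT 2 (0.105), polymerase genes without MUT 1 (0.07) and ribosomal protein genes without MUT 4 (0.221).

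In blastocysts labelled Taf12 MUT, compared with WT to ask how their expression differs, 64 genes rose and 120 fell. H1f2, a linker histone, rose 22.7-fold, to 19.2 ± 6.96 from 0.846 ± 0.693 FPKM (log2 3.48, SE 0.42, adjusted p = 0.0035). Plat, the tissue plasminogen activator, rose 8.06-fold, to 5080 ± 3920 from 629 ± 104 (adjusted p = 0.0118, 4.49-fold without MUT 1), and Car4, a carbonic anhydrase, rose 8.46-fold (adjusted p = 0.0118). H2bc4, a core histone, rose 10.3-fold (5.66 without MUT 2), Nlrp14, an oocyte gene, 12.5-fold, Tmprss12, a serine protease, 21.7-fold (66.3 without WT 1), and Bean1 17-fold. Of the WT only WT 4 had reads of Nlrp14 and Bean1 (at least 21.3-fold and 14.4-fold without it). Cnn1, a calponin, was at 6.33 ± 1.92 FPKM with 0 reads in WT, at least 11.4-fold higher. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, had 0 reads in MUT against 124 ± 93 FPKM in WT, at least 35.2-fold lower (adjusted p = 0.00264). Oas1f, of an antiviral synthetase family, fell at least 29.7-fold from 88.4 ± 38.5 (adjusted p = 3.85e-05), Nav3 at least 18.9-fold, Rbfaos at least 19.8-fold (10.6 without WT 2) and Stat2, an interferon signal transducer, at least 17.2-fold. Thumpd2 fell 133-fold on 2 reads in MUT 2 (interval 36.7 to 1100, at least 28.3 without it, adjusted p = 5.56e-05), Usp3, a deubiquitinase, 88.6-fold (198 without MUT 3) and Fgf10, a growth factor, 29.2-fold (19.4 without MUT 1 or MUT 3, 17.3 without WT 1, at least 67 without MUT 2).

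Cholesterol synthesis and uptake fell as a group in Taf12 MUT blastocysts (20 genes, median −1.0, adjusted p = 1.51e-06), with adjusted p = 0.407 with an estimated correlation. Of its members 3 fell, and 9 adjusted over the list alone. Nsdhl fell 4.74-fold, to 1.51 ± 0.469 from 7.17 ± 1.04 FPKM (adjusted p = 0.0256), and Fdps 3.38-fold. Naive pluripotency and epiblast genes fell (23 genes, median −0.76, adjusted p = 0.000257, adjusted p = 0.407 with an estimated correlation), with 2 members called and 3 adjusted over the list alone, and a median of −0.39 without MUT 1. That library stood apart from MUT 2 and MUT 3, at 0.919 on the first principal component (0.072 and 0.083), with 11875 genes above 0 (14612 and 14196) and 3.59% mitochondrial reads (1.97 and 2.91%). Fgf4, the growth factor the epiblast signals with, was at 1.68 ± 2.91 against 77.5 ± 90.1 FPKM, 46.2-fold lower (22.4 without WT 1, at least 63 without MUT 1, adjusted p = 0.0111), and Tdgf1, a Nodal coreceptor, fell 7.69-fold. Utf1 was at 58.2 ± 47.7 against 261 ± 80.9 (adjusted p = 0.0796). Cytosolic ribosomal protein genes fell (79 genes, median −0.26, adjusted p = 3.72e-08, adjusted p = 0.622 with an estimated correlation), 4 of them called and 13 adjusted over the list alone, such as Rps23 (1.71-fold lower).

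TFIID, polymerase II and histone genes stood higher in the same embryos. TFIID subunits rose (14 genes, median 0.53, adjusted p = 0.00722, adjusted p = 0.188 with an estimated correlation), with Taf13 called, 3 members higher adjusted over the list alone and Taf6 at 559 ± 256 against 230 ± 27.9 FPKM (adjusted p = 0.0873). RNA polymerase II and its general factors rose (32 genes, median 0.14, adjusted p = 0.0219, adjusted p = 0.622 with an estimated correlation). Polr2a, the largest polymerase subunit, rose 3.03-fold and Gtf2a1 2.69-fold, with 4 members higher and 1 lower adjusted over the list alone. Histone genes rose (14 genes, median 0.29, adjusted p = 0.00749, adjusted p = 0.407 with an estimated correlation), where H1f2, H2bc4 and H3f3b (1.78-fold) were called over all genes and over the list alone. Mitochondrially encoded transcripts stood higher (12 genes, median 0.35, adjusted p = 0.0271, adjusted p = 0.622 with an estimated correlation) with 0 called, mt-Nd5 being at 8670 ± 2820 against 6070 ± 1090, and their share of reads was 2.82 ± 0.813% against 2.38 ± 0.157%. SAGA subunits did not pass (18 genes, adjusted p = 0.505, median 0.17, mean −0.03, 1 lower).

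limma called 184 of 12751 genes in this comparison, voom called 188 and 2052 were under an unadjusted p of 0.05. The authors' table, with WT and HET together as control, listed 1294 (431 higher, 863 lower). The count was 78 without WT 2, 114 without WT 4, 104 without WT 5 and 121 without MUT 1. Taf13, H1f2, Car4, Plat, Pck2, Oas1f, Thumpd2, Usp3, Nav3, Rbfaos, Polr2a and Fgf4 were called without any library. The other named calls were lost without WT 2 (Nlrp14, Tmprss12, Bean1, Cnn1, Stat2, Fgf10, Gtf2a1, Tdgf1, Rps23, Nsdhl and Fdps, adjusted p = 0.0518 to 0.0754) or MUT 1 (all of these but Tdgf1, and H3f3b, adjusted p = 0.054 to 0.131). H2bc4 was lost without MUT 2 alone (0.057), and Utf1 was called without any 1 of MUT 1, MUT 2 or MUT 3 (0.0281, 0.049 and 0.0409). Some of these were lost without WT 1, WT 3, WT 4, WT 5, MUT 2 or MUT 3 too, at adjusted p up to 0.0916 (Fdps without WT 5). Taf6 was called without MUT 3 (0.00643). The polymerase group did not pass without WT 1 (0.0779) or MUT 3 (0.301), nor the mitochondrial group without WT 3 (0.0678), WT 4 (0.0763), MUT 1 (0.565) or MUT 3 (0.254).

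In Taf12 HET blastocysts, which carry 1 mutant allele by their label, no gene was called. The smallest p-values were those of Lca5l (0 reads against 13.4 ± 8.92 FPKM in WT, adjusted p = 0.245), Ints5, an Integrator subunit (111 ± 35.8 against 40.5 ± 8.74, adjusted p = 0.443), and Ap2a1, an adaptor complex subunit (58.7 ± 14.4 against 26.3 ± 6.34, adjusted p = 1). Cholesterol synthesis stood lower (20 genes, median −0.66, adjusted p = 4.59e-10), as did ribosome biogenesis (40 genes, median −0.11, 0.033) and p53 targets (27 genes, median −0.26, 0.0389). Parietal endoderm (12 genes, median 0.54) and extraembryonic ectoderm (17 genes, median 0.34) stood higher, at 0.0195 each. With an estimated correlation adjusted p = 0.487 for cholesterol synthesis and adjusted p = 0.619 to 0.769 for the other 4, and 0 of their members were called over all genes or adjusted over the list alone. Of these groups the cholesterol list alone passed without each library. The other 4 did not without WT 5, HET 1 or HET 2 (adjusted p = 0.0548 to 0.334), and some not without WT 2 (0.0867), WT 3 (0.261), WT 4 (0.241) or HET 3 (0.0503). limma called 0 of 12751 genes, 447 were under an unadjusted p of 0.05 and voom called 0, with 1 call without HET 2 or without HET 3.

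Outgrowths tested whether Taf12 MUT blastocysts could go on to form the cell types that appear in culture. The visceral endoderm group, the outer layer that nourishes the early embryo, was lower in MUT for all 14 of its genes (median log2 fold change −3.29, adjusted p = 6.5e-07, adjusted p = 0.375 with an estimated correlation), also adjusted over the list alone. Apoe, an apolipoprotein, fell 26.2-fold, to 16 ± 7.92 from 420 ± 317 FPKM (16.6-fold without WT 2, adjusted p = 0.000117), and Cited1, a transcriptional coregulator, 80.9-fold, to 0.494 ± 0.346 from 39.9 ± 22.3 (adjusted p = 3.22e-05). Apom had 1 read in MUT, in MUT 2 (912-fold lower, interval 163 to 36100, at least 70.6 without it). Primitive endoderm genes fell too (12 of 18, 13 adjusted over the list alone, median −1.9, adjusted p = 0.00029, adjusted p = 0.451 with an estimated correlation), with Amn, a subunit of the endocytic receptor cubam, 45.4-fold lower (78.1 without MUT 1, 29.9 without WT 2) and Sparc, a matrix glycoprotein, 7.95-fold lower. Of parietal endoderm genes 8 fell and 1 rose (15 genes, 10 and 1 adjusted over the list alone, median −1.63, adjusted p = 0.0185, adjusted p = 0.451 with an estimated correlation), the riser being Nid1, a basement membrane gene, 3.16-fold higher.

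Trophectoderm genes rose in the same outgrowths (11 of 22 higher and 2 lower, 12 and 3 adjusted over the list alone, median 0.87, adjusted p = 0.0185, adjusted p = 0.419 with an estimated correlation). Krt8 and Krt18, the keratins of the trophectoderm, rose 5.02-fold (20000 ± 5400 against 3980 ± 1440 FPKM, adjusted p = 0.000206) and 4.19-fold (5730 ± 959 against 1370 ± 386, adjusted p = 0.00011). The largest rises included Atp12a, a proton pump with 584 ± 456 FPKM in MUT and 0 reads in WT (at least 128-fold, adjusted p = 1.48e-05), and Dppa1, 93.5-fold (605 ± 360 against 6.46 ± 9.07). They also included Adh1, an alcohol dehydrogenase (942-fold), Elobl (322-fold), Snap91, a clathrin assembly gene (71.7-fold), Trpv5, a calcium channel (55.4-fold), Slc6a14, an amino acid transporter (36.2-fold), and Ctsll3, a cathepsin family gene (10.5-fold). Without WT 3 the folds of these 7, from Dppa1 on, were 281, 10600, 714, 161, 10500, 78 and 58.6, and Adh1 was at 407 without MUT 2 and Trpv5 at 31.9 without MUT 4. Giant cell and placental genes went both ways (17 genes, 3 higher and 5 lower also adjusted over the list alone, adjusted p = 0.817, median 0.6 and test upward, mean −0.48). Cts7, a placental cathepsin, fell 3790-fold, to 0.236 ± 0.349 from 893 ± 200 FPKM (13800 without MUT 3, adjusted p = 2.17e-08), and Peg10, an imprinted gene the placenta requires, rose 12.3-fold. Other large falls were those of Ceacam15 (720-fold, 1360 without MUT 4), Pxylp1 (1 read, in MUT 2, 1620-fold, interval 291 to 64000, at least 124 without it), Tfpi2, a protease inhibitor (102-fold, 2570 without MUT 3), Cyp26a1, which degrades retinoic acid (29.2-fold, 60.5 without MUT 2), Ret, a receptor kinase (25.4-fold, reads in MUT 3 alone of the MUT, at least 70.1 without it), Fads2, a fatty acid desaturase (14.6-fold, 23.2 without MUT 1), and Cpe, a carboxypeptidase (0 reads in MUT, at least 14.5-fold).

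**Figure D2:**
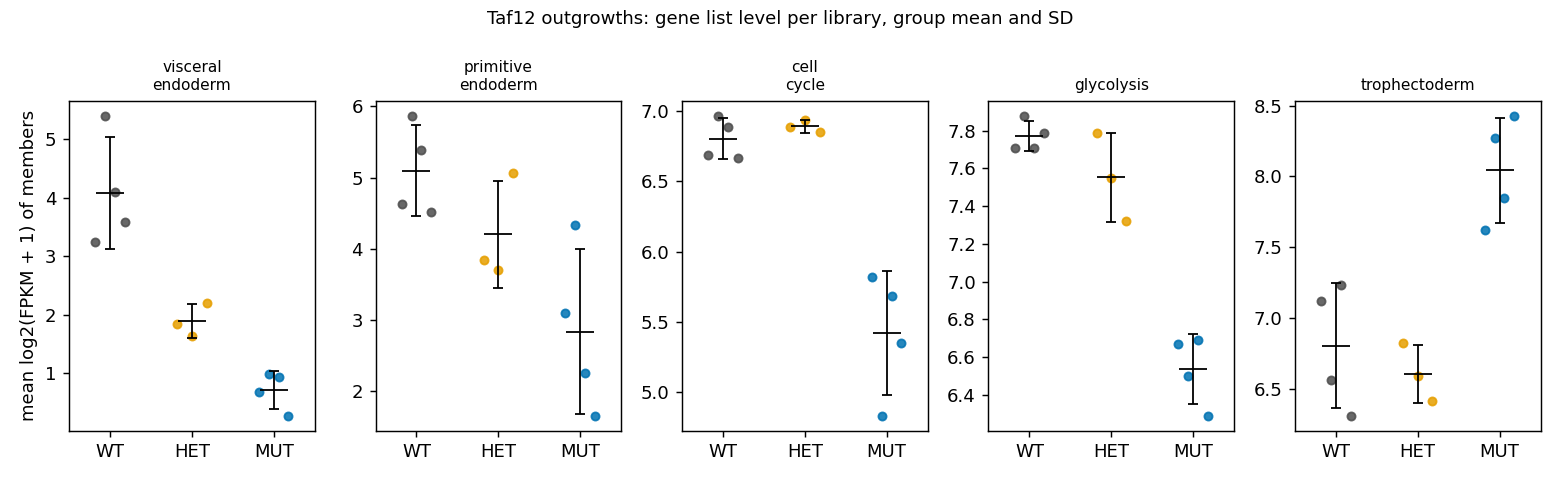
Mean log2(FPKM + 1) of 5 gene groups in each Taf12 outgrowth library (points) by genotype, with group means and SD. Visceral endoderm averages 4.08 ± 0.95 in WT, 1.9 ± 0.29 in HET and 0.72 ± 0.32 in MUT, and trophectoderm 6.8 in WT and 8.04 in MUT.

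Cell cycle, glycolysis and ribosome genes were lower in Taf12 MUT outgrowths. Of 35 cell cycle genes 29 fell and 1 rose (29 and 2 adjusted over the list alone, median −1.33, adjusted p = 4.44e-09, adjusted p = 0.419 with an estimated correlation). Kif11, a mitotic motor, fell 5.32-fold (240 ± 108 against 1280 ± 214 FPKM) and Mcm6, of the replicative helicase, 2.35-fold. Glycolysis genes fell (13 of 20, 14 adjusted over the list alone, median −1.05, adjusted p = 2.24e-05, adjusted p = 0.332 with an estimated correlation), with Pkm 6.01-fold lower (429 ± 66.1 against 2580 ± 319) and Eno1 5.52-fold. Ribosome biogenesis fell (27 of 40 lower and 1 higher, 31 and 2 adjusted over the list alone, median −0.63, adjusted p = 2.54e-08, adjusted p = 0.0183 with an estimated correlation), with Ncl, the nucleolin gene, 4.19-fold and Npm1 1.84-fold lower. Cytosolic ribosomal protein genes fell (60 of 78, 63 adjusted over the list alone, median −0.63, adjusted p = 2.66e-15, adjusted p = 0.451 with an estimated correlation), with Rpsa 2.99-fold lower. Cholesterol synthesis had 13 of 20 lower and 2 higher (14 and 2 adjusted over the list alone, median −0.84, adjusted p = 0.00122, adjusted p = 0.419 with an estimated correlation). Of p53 targets 12 fell and 2 rose (27 genes, 16 and 2 adjusted over the list alone, median −0.64, adjusted p = 0.00211, adjusted p = 0.451 with an estimated correlation), including Bax, a promoter of cell death (1.77-fold lower).

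Histone, mitochondrial and TFIID transcripts rose in Taf12 MUT outgrowths. Histone genes had 8 of 16 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.75, adjusted p = 0.00181, adjusted p = 0.091 with an estimated correlation), H2bc4 and H1f2 each by 13.6-fold. Mitochondrially encoded transcripts rose in 9 of 10 genes, also adjusted over the list alone (median 0.96, adjusted p = 0.000103, adjusted p = 0.419 with an estimated correlation), mt-Nd5 2.13-fold. TFIID subunits had 6 of 15 higher and 1 lower, also adjusted over the list alone (median 0.47, adjusted p = 0.0279, adjusted p = 0.283 with an estimated correlation). They included Taf6 (2.85-fold) and Taf4b (2.66-fold), and the group did not pass without MUT 3 (0.0692). Polymerase II and its general factors had 10 higher and 3 lower of 32 (10 and 4 adjusted over the list alone, adjusted p = 0.207), with Gtf2b 3.04-fold and Polr2a 2.19-fold higher. SAGA subunits had 3 higher and 5 lower of 18 (also adjusted over the list alone, adjusted p = 0.93, median −0.08, test upward). Naive pluripotency genes had 3 higher and 4 lower of 17 (also adjusted over the list alone, adjusted p = 0.93), Dppa5a rising 9-fold while Esrrb had 0 reads in MUT (at least 9.78-fold lower, 4.46 without WT 2).

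Stress groups were mixed and none passed as a group. The integrated stress response had 4 higher and 8 lower of 20 (also adjusted over the list alone, adjusted p = 0.103), with Asns, the asparagine synthetase, 2.18-fold lower and Ddit4, an inhibitor of growth signalling, 3.72-fold higher. Heat shock and folding genes had 5 higher and 8 lower of 19 (5 and 9 adjusted over the list alone, adjusted p = 0.34), with Hsp90aa1 3.29-fold higher and Hspd1, a mitochondrial chaperonin, 2.89-fold lower. Immediate early genes had 5 higher and 4 lower of 18 (also adjusted over the list alone, adjusted p = 0.802, median −0.16, test upward), with Myc 2.55-fold higher and Fosl1 3.6-fold lower. Apoptosis genes had 2 higher and 6 lower of 24 (also adjusted over the list alone, adjusted p = 0.613), with Birc5, the survivin gene, 3.41-fold lower. limma called 4956 of 13068 genes (2349 higher, 2607 lower), 2913 of them at 2-fold or more, with 6178 under an unadjusted p of 0.05, and voom called 5048. The authors' table listed 6671 (3299 higher, 3372 lower).

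Taf12 HET outgrowths had lower visceral endoderm transcripts as a group (14 genes, median −1.98, adjusted p = 7.11e-21, adjusted p = 0.128 with an estimated correlation). None of the 14 was called over all genes and 10 fell adjusted over the list alone. Apom was at 2.17 ± 2.66 against 66.3 ± 52.6 FPKM in WT (adjusted p = 0.0893, and 0.0378 without HET 1), Soat2 at 1.2 ± 0.258 against 9.46 ± 6.99 and Ttr at 3.98 ± 3.09 against 40.7 ± 22.8. Primitive endoderm (18 genes, median −0.79, adjusted p = 5.2e-05), p53 targets (27, −0.23, 0.000113), naive pluripotency (17, −0.48, 0.00343) and parietal endoderm genes (15, −0.5, 0.0345) stood lower. Ribosomal protein genes (78, 0.17, 1.04e-10), mitochondrially encoded transcripts (10, 0.18, 0.00943) and cell cycle genes (35, 0.15, 0.0345) stood higher. For these 7 adjusted p = 0.776 to 0.841 with an estimated correlation, and 0 members were called over all genes, with 1 p53 target lower adjusted over the list alone. Only the visceral endoderm, primitive endoderm and ribosomal groups passed without each library. Naive pluripotency did not without WT 2 (0.0969) or WT 3 (0.0616), p53 targets without WT 4 (0.0641), and mitochondrial transcripts without WT 2 (0.193) or HET 1 (0.147). Parietal endoderm did not without WT 2 (0.193), WT 4 (0.0641), HET 1 (0.457) or HET 2 (0.299), nor cell cycle without WT 1 (0.16), WT 4 (0.352), HET 1 (0.0668) or HET 2 (0.154).

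limma called 4 of 13068 genes in HET outgrowths, voom called 0, and 571 were under an unadjusted p of 0.05. Zfp7, a zinc finger gene, fell 3.43-fold, to 7.96 ± 0.925 from 27.3 ± 3.18 FPKM (log2 −1.66, SE 0.18, adjusted p = 0.0288). The other 3 were named after their values were seen: Fabp1, a fatty acid binding protein of endoderm (log2 −1.9, adjusted p = 0.0344), and the predicted genes Gm42989 and Gm35867 (log2 2.95 and 2.45, adjusted p = 0.0461 each). The count was 0 without WT 1 or WT 2, 2 without WT 3, 1 without WT 4, HET 2 or HET 3, and 7 without HET 1. Zfp7 was not called without WT 1 (0.173), WT 2 (0.127), WT 4 (0.0551), HET 2 (0.0783) or HET 3 (0.0667).

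Taf13 MUT blastocysts were compared with WT to ask whether this TFIID subunit matters at the same stage, and endoderm genes were among those lower. Sox17, a transcription factor of the primitive endoderm, had 0 reads in MUT against 9.23 ± 3.91 FPKM in WT, at least 230-fold lower (log2 −3.28, SE 0.43, adjusted p = 0.0157). Serpinh1, a collagen chaperone, fell 26.3-fold, to 5.14 ± 1.99 from 135 ± 99.4 (17.3-fold without WT 2, adjusted p = 0.0157). Gmds, an enzyme of GDP-fucose synthesis (at least 29.9-fold), Ets2, a transcription factor (at least 43.8-fold), and Ttyh3 (at least 9.72-fold, 6.2 without WT 2) had 0 reads in MUT. Adck2 fell 224-fold on 1 read in MUT 3 (interval 39.9 to 8870, at least 23.9 without it) and Rtn1 125-fold on 2 reads in MUT 1 (interval 34.4 to 1040, at least 28.5 without it). Stfa1 fell 25.7-fold (17.1 without MUT 1 or MUT 2, at least 21.7 without MUT 3) and Ythdc2, an RNA helicase, 18.7-fold (60.5 without MUT 1, 12.4 without MUT 2). Uap1l1 rose 2.44-fold, to 185 ± 12.3 from 75.8 ± 9 FPKM (adjusted p = 0.0096), and Ell, an elongation factor of RNA polymerase II, 2.83-fold (adjusted p = 0.047). The third riser, the clone AA474408 (log2 3.29, adjusted p = 0.0259), was named after its value was seen.

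As groups, primitive endoderm (16 genes, median −0.96, adjusted p = 0.0361) and parietal endoderm (11 genes, median −0.9, 0.042) stood lower in Taf13 MUT blastocysts. For both adjusted p = 0.619 with an estimated correlation, with 1 member of each called and 6 and 4 lower adjusted over the list alone. Gata4, an endoderm transcription factor, had 0 reads against 19.8 ± 11.8 FPKM (adjusted p = 0.114, and 0.0279 without WT 3) and Pdgfra was at 7.15 ± 2.65 against 18.2 ± 3.05. Ribosomal protein genes stood lower (79 genes, median −0.1, 0.0361, adjusted p = 0.728 with an estimated correlation) and polymerase II genes higher (32 genes, median 0.16, 0.0361, adjusted p = 0.619 with an estimated correlation), with 0 members called. These groups did not pass without WT 2 (primitive endoderm 0.114, parietal endoderm and polymerase 0.171), MUT 2 (0.258, 0.231, and 0.115 for the other 2) or MUT 3 (0.157 for all but the ribosomal genes). Without WT 4 parietal endoderm and ribosomal genes were at 0.121, and the ribosomal genes were at 0.383 without WT 1 and 0.404 without MUT 1. TFIID subunits did not pass (14 genes, 0 called, adjusted p = 0.67). The embryo sex list, Xist and Y-linked genes, did not pass (5 genes, median −3.48, adjusted p = 0.103), with 4 lower and 1 higher adjusted over the list alone. All 4 WT libraries had Ddx3y, a Y-linked gene, at 113 FPKM or more, while MUT 1 and MUT 3 had 0 reads of it and MUT 2 had 142.7.

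limma called 16 of 11975 genes in Taf13 MUT blastocysts (3 higher, 13 lower), voom called 1, and 1118 were under an unadjusted p of 0.05. The authors' table listed 532 (131 higher, 401 lower). With the Ddx3y level as a covariate, chosen after seeing the data, limma called 0. The count was 9 without WT 1 or WT 4 and 26 without MUT 2 or MUT 3. Uap1l1, Stfa1, Gmds and Rtn1 were called without any library. Sox17 was not without WT 1 (0.0592) or WT 4 (0.0508), Serpinh1 not without WT 1 (0.0592) or MUT 1 (0.0506), and Adck2 not without WT 1 (0.0516), WT 4 (0.0508) or MUT 1 (0.0506). Ell and Ets2 were not without any 1 of the 7 libraries (0.0508 to 0.103), Ttyh3 held only without WT 3 (0.081 to 0.157 for the others), and Ythdc2 only without WT 1 or MUT 1 (0.067 to 0.122).

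In Taf13 HET blastocysts no gene was called. Gramd3, Thrsp and Dusp8, a phosphatase gene, had 0 reads in WT and 9.65 ± 5.45, 8.89 ± 8 and 77.4 ± 17.4 FPKM in HET (adjusted p = 0.319 each, with Gramd3 at 0.00416 without HET 3). Trophectoderm genes stood higher as a group (21 genes, median 0.28, adjusted p = 1.16e-05, adjusted p = 0.605 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. limma called 0 of 11975 genes, 519 were under an unadjusted p of 0.05 and voom called 0. There was 1 call without WT 3 or HET 3 and 2 without HET 4.

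Epiblast genes were lower in the Taf13 MUT embryos at E6.5, where the comparison with WT asks whether embryos labelled mutant go through implantation. Pou5f1, the pluripotency factor of the epiblast, had 0 reads in the 2 MUT libraries against 366 ± 121 FPKM in WT (n = 4), at least 571-fold lower (log2 −8.46, SE 0.43, adjusted p = 1.72e-08). Tdgf1, a Nodal coreceptor, had 1 read, in MUT 2, against 1630 ± 743 FPKM in WT (21200-fold lower, interval 3810 to 838000, at least 3610 without it and 10700 without MUT 1). All 15 postimplantation epiblast genes were lower when adjusted over the list alone and 9 over all genes (median −3.23, adjusted p = 2.97e-17, adjusted p = 0.00631 with an estimated correlation). Otx2, a homeobox gene, fell at least 455-fold, Slc7a3, an arginine transporter, 1030-fold, Fgf5 84.7-fold and Fgf8 36-fold. Naive pluripotency genes had 12 lower and 2 higher of 22 (13 and 5 adjusted over the list alone, median −1.48, adjusted p = 8.69e-07, adjusted p = 0.00295 with an estimated correlation), with Nanog at 0.0586 ± 0.0829 against 8.86 ± 2.41 (151-fold lower) and Dppa4 13.2-fold lower. Without MUT 1, then without MUT 2, the folds were 619 and 3130 for Slc7a3, 42.4 and at least 928 for Fgf5, 18.2 and 1400 for Fgf8, 75.5 and at least 306 for Nanog, and 7.64 and 48 for Dppa4. Gng3 fell 142-fold and Ina, a neuronal intermediate filament gene, at least 84.8-fold. Slain1 fell at least 5.49-fold from 60 reads in WT.

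In the same embryos the anterior visceral endoderm group had 7 lower and 1 higher of 11, also adjusted over the list alone (median −2.33, adjusted p = 5.44e-07, adjusted p = 0.0206 with an estimated correlation). Lefty1, a Nodal inhibitor, had 0 reads in MUT (at least 300-fold lower), Gsc fell 69.5-fold (34.8 without MUT 1, at least 70.3 without MUT 2) and Sfrp1, a Wnt inhibitor, 32.6-fold (16.8 and 593). Primitive streak and mesoderm genes fell (6 of 21, 10 adjusted over the list alone, median −1.88, or −1.0 without MUT 1, adjusted p = 2.39e-05, adjusted p = 0.314 with an estimated correlation), with Eomes 7.83-fold and Bmp4 5.39-fold lower. Extraembryonic ectoderm genes fell (4 of 18, 7 adjusted over the list alone, median −1.22, adjusted p = 0.000301, adjusted p = 0.434 with an estimated correlation), but without MUT 1 the group did not pass (median −0.24, 0.639). Elf5, a trophoblast stem cell factor, fell 2.97-fold (6.22 ± 8.05 against 18.4 ± 1.48 FPKM, adjusted p = 0.0188, 1.55 without MUT 1 and 35.3 without MUT 2) and Esrrb 80.5-fold (2.76 ± 3.9 against 222 ± 183, adjusted p = 0.00602, 40.2 and at least 149).

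Visceral endoderm genes of E6.5 MUT had 5 higher and 2 lower of 19 (6 and 3 adjusted over the list alone, median 0.19, adjusted p = 0.455), with Soat2 2.45-fold higher and Rbp4, a retinol carrier, 3.76-fold lower. Primitive endoderm genes rose (10 of 20, 12 adjusted over the list alone, median 1.24, or 0.63 without MUT 1, adjusted p = 6.86e-07, adjusted p = 0.245 with an estimated correlation), with Col4a2 5.07-fold and Lama1 6.87-fold higher (Lama1 4.19 without MUT 1). Parietal endoderm genes rose (7 of 15, 8 adjusted over the list alone, median 1.51, adjusted p = 0.000255, adjusted p = 0.433 with an estimated correlation), with Sparc 2.25-fold higher. Genes of the decidua and uterus, the maternal tissue around the embryo, rose (11 of 18, 14 adjusted over the list alone, median 2.63, adjusted p = 6.86e-07, adjusted p = 0.34 with an estimated correlation), with Dio3 21.9-fold, Des 8.79-fold and Igfbp1 8.03-fold higher. Their mean log2(FPKM + 1) was 5.18 ± 0.23 in MUT and 2.61 ± 1.17 in WT, and 4.34 in WT 3 and 4.09 in HET 8, whose epiblast means were 5.56 and 5.98. Of WT, Lama1 was also highest in WT 3, so maternal tissue stays open for the endoderm rises. Blood and immune genes stood higher (10 genes, 1 called also adjusted over the list alone, median 2.37, adjusted p = 0.009, adjusted p = 0.566 with an estimated correlation) but did not pass without MUT 2 (0.194). Among the largest rises were the uterine gene Hoxa10 (763 ± 42.8 against 71.2 ± 104 FPKM, 10.7-fold), Tdo2 (12.7-fold), Gatm (11.6-fold) and Ccr2 (0 reads in WT, at least 14.8-fold). Others were Vnn1 (32.5-fold, 51.1 without WT 2), Elfn1 (27.9-fold), Cdhr5 (18.5-fold) and Gda (6.78-fold). Without WT 3 the folds were 11.7 for Lama1, 76.2 for Dio3, 28.2 for Des, 38.7 for Hoxa10, 54.9 for Tdo2, 42.1 for Gatm, 162 for Gda and at least 20.7 for Cdhr5, which no other WT library held. Without MUT 1, then without MUT 2, Vnn1 was at 13.6 and 51.3 and Elfn1 at 10.2 and 45.6, and Dio3 at 13.9 without MUT 2.

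**Figure D3:**
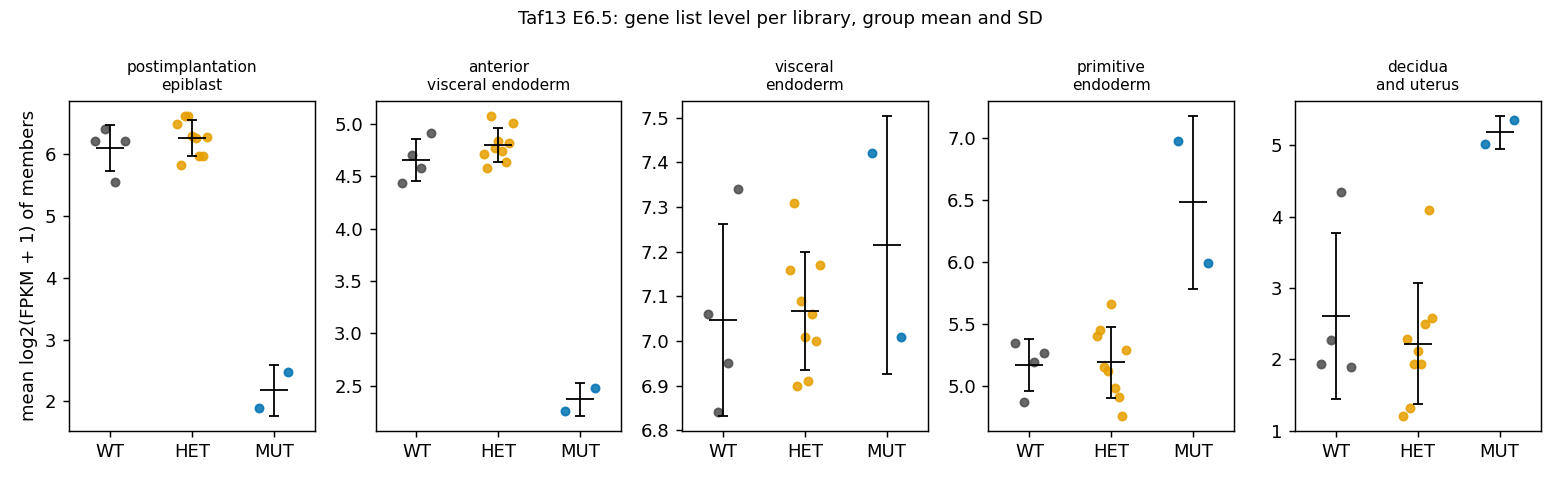
Mean log2(FPKM + 1) of 5 gene groups in each Taf13 E6.5 library (points) by genotype, with group means and SD. Postimplantation epiblast averages 6.1 ± 0.37 in WT and 2.18 ± 0.41 in MUT, and visceral endoderm 7.05 and 7.22.

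In E6.5 MUT ribosome biogenesis genes fell (13 of 40, 14 adjusted over the list alone, median −0.56, adjusted p = 6.86e-07, adjusted p = 0.245 with an estimated correlation), with Npm1 2.48-fold lower. Cytosolic ribosomal protein genes fell (5 of 78, also adjusted over the list alone, median −0.52, adjusted p = 6.86e-07, adjusted p = 0.683 with an estimated correlation). Cell cycle genes stood lower (5 of 35 called, also adjusted over the list alone, median −0.15, adjusted p = 0.0205, adjusted p = 0.566 with an estimated correlation), with the cyclin genes Ccnd1 6.67-fold and Ccne1 3.91-fold lower. Heat shock and folding genes had 6 lower and 1 higher of 19, also adjusted over the list alone (median −0.36, adjusted p = 0.009, adjusted p = 0.433 with an estimated correlation), the riser being Hspb1, 3.14-fold. Polymerase II and its general factors had 4 lower and 1 higher of 32 (5 and 1 adjusted over the list alone, median −0.36, adjusted p = 0.0199) and cholesterol synthesis 1 lower of 21, also adjusted over the list alone (median −0.39, adjusted p = 0.0296). For each of these 2 adjusted p = 0.505 with an estimated correlation. Mitochondrially encoded transcripts stood higher (9 genes, 0 called, median 1.48, adjusted p = 0.0251, adjusted p = 0.683 with an estimated correlation). TFIID subunits had 2 lower of 14, also adjusted over the list alone (adjusted p = 0.585, median 0.07, mean −0.04), and p53 targets had 5 higher and 3 lower of 26 (8 and 5 adjusted over the list alone, adjusted p = 0.485).

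At E6.5 limma called 1880 of 14417 genes in MUT (958 higher, 922 lower), 1410 of them at 2-fold or more, with 4164 under an unadjusted p of 0.05, and voom called 2210. The authors' table listed 4108 (1778 higher, 2330 lower). Only 2 MUT embryos were measured, and a fit without 1 of them assumes that the lone sample varies like the other groups. The count was 554 without MUT 1 and 1238 without WT 2. All epiblast, anterior visceral endoderm, mesoderm, ribosome and cell cycle genes named above but Slain1, together with Col4a2, Dio3, Rbp4 and Hspb1, were called without any library. Without MUT 1 the calls of Ccr2 (0.157), Hoxa10 (0.146), Gda (0.202), Elfn1 (0.225), Vnn1 (0.334), Cdhr5 (0.279), Gatm (0.126), Tdo2 (0.151), Des (0.0783), Igfbp1 (0.146), Lama1 (0.148), Sparc (0.0555), Esrrb (0.138), Elf5 (0.403), Soat2 (0.0568) and Slain1 (0.21) were lost. Without MUT 2 those of Ccr2, Hoxa10, Gda, Vnn1, Cdhr5, Gatm, Tdo2, Sparc and Slain1 were lost (0.0558 to 0.159). Ccr2, Gda, Cdhr5, Slain1 and Vnn1 were lost too without WT 1, WT 2, WT 3 or WT 4 in some cases, at up to 0.105 (Gda without WT 2). Groups that did not pass without MUT 1 were extraembryonic ectoderm (0.639), heat shock (0.124), polymerase II (0.0944), mitochondrial (0.471), cholesterol (0.429) and cell cycle genes (0.0514). Cell cycle did not pass without WT 1 either (0.0664), cholesterol not without WT 2 (0.0802) and mitochondrial transcripts not without WT 4 (0.16).

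Taf13 HET embryos at E6.5 had no called gene, with epiblast at 6.27 ± 0.29 and decidua at 2.22 ± 0.84 (mean log2(FPKM + 1), n = 9). The smallest p-values were those of Itpk1, an inositol kinase (32.1 ± 10.6 against 55.4 ± 3.73 FPKM), Prkdc, the DNA-dependent protein kinase (10.4 ± 1.88 against 16.4 ± 3.08), and Slc24a4, a cation exchanger (27.3 ± 4.41 against 37.9 ± 3.4), each with adjusted p = 1. Ribosomal protein (78 genes, median 0.11, adjusted p = 0.000175), oxidative phosphorylation (40 genes, median 0.09, 0.00945) and mesoderm genes (21 genes, median 0.27, 0.00945) stood higher as groups. With an estimated correlation adjusted p = 0.986 for each, and 0 members were called, also adjusted over the list alone. Without WT 1 the medians of the first 2 were −0.04 (0.658) and −0.02 (0.818), without WT 4 they did not pass (0.593 and 0.607), and without WT 3 mesoderm did not (0.876). With the replicate number as a block the first 2 were lower (−0.26, adjusted p = 1.3e-08, and −0.22, 0.0022). limma called 0 of 14417 genes, 174 were under an unadjusted p of 0.05 and voom called 0.

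**Figure D4:**
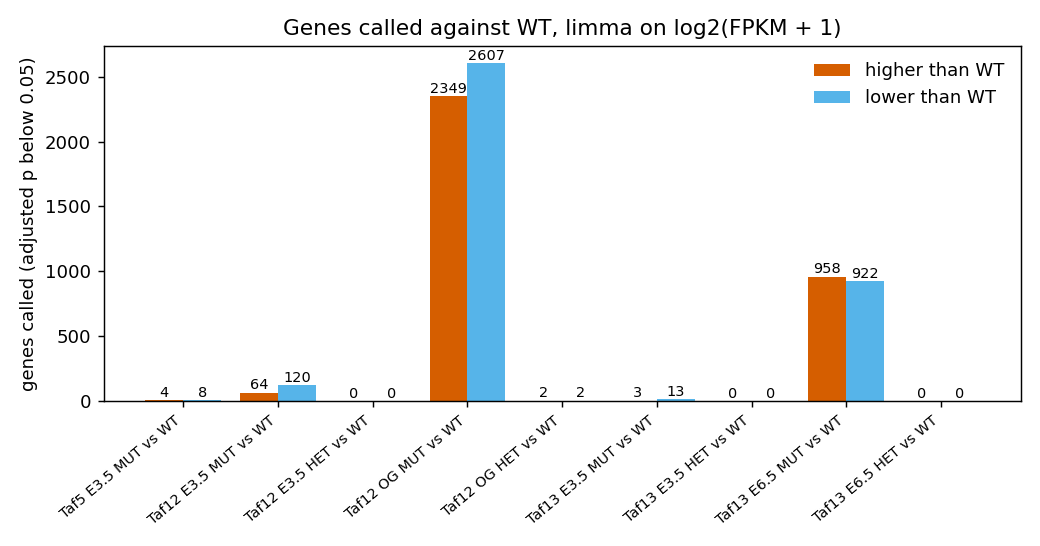
Number of genes called (adjusted p under 0.05) higher and lower in each comparison, as bars. Taf12 MUT outgrowths have 2349 higher and 2607 lower, Taf13 MUT at E6.5 958 and 922, and the blastocyst comparisons 184 in all or fewer.

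Whether the effect of the mutation differed between stages was tested as the difference of the MUT effects, each against its own WT. In the Taf12 line 1658 of 15064 genes differed between outgrowth and blastocyst (815 higher and 843 lower in outgrowth, 3727 under an unadjusted p of 0.05, 1439 by voom). Visceral endoderm (11 of 16 lower, 12 adjusted over the list alone, median −2.87, adjusted p = 4.26e-10), cell cycle (13 of 35, 19 adjusted over the list alone, −1.0, 3.44e-11) and glycolysis genes (6 of 20, 7 adjusted over the list alone, −0.78, 1.67e-05) had a lower MUT effect in outgrowths than in blastocysts. For these 3 adjusted p = 0.0857 with an estimated correlation. Trophectoderm (5 of 22, 8 higher and 1 lower adjusted over the list alone, 1.04, 0.00532, adjusted p = 0.711 with an estimated correlation) and naive pluripotency genes (4 of 23, 4 higher and 1 lower adjusted over the list alone, 0.64, 0.0186, adjusted p = 0.736 with an estimated correlation) moved the other way. Naive pluripotency did not pass without E3.5 MUT 1 (0.221) or OG WT 4 (0.122).

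In the Taf13 line 722 of 16239 genes differed between E6.5 and E3.5 (393 higher and 329 lower at E6.5, 3035 under an unadjusted p of 0.05, 703 by voom). Tdgf1 and Pou5f1 were lower by the difference (log2 −9.69 and −8.57), and Osbpl5, Mthfd1l, a mitochondrial folate enzyme, and Wwox, an oxidoreductase, higher (6.76, 6.72 and 6.32). Postimplantation epiblast (8 of 16, 13 adjusted over the list alone, median −2.63, adjusted p = 4.97e-21, adjusted p = 0.000268 with an estimated correlation), naive pluripotency (10 of 24, 12 lower and 3 higher adjusted over the list alone, −1.41, 2.92e-08, adjusted p = 0.00209 with an estimated correlation) and anterior visceral endoderm genes (7 of 11, 7 lower and 2 higher adjusted over the list alone, −2.35, 2.4e-06, adjusted p = 0.000984 with an estimated correlation) passed both tests. The count was 314 without E6.5 MUT 1 and 461 without E6.5 WT 2, where the lone MUT sample is assumed to vary like the other groups. Osbpl5 (0.0595) and Wwox (0.064) were not called without E6.5 MUT 1.

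Whether the 3 lines shared a response was tested in blastocysts. No gene called in 1 line was called in the same direction in another. At an unadjusted p under 0.01, Taf5 and Taf12 MUT shared 16 genes higher (2.76 expected, Fisher's exact test adjusted p = 7.38e-08) and 22 lower (5.45 expected, 7.64e-08), among them Polr2a, higher, and Myc and Rps9, lower. Taf12 and Taf13 MUT shared 11 higher (2.41 expected, adjusted p = 8.22e-05) and 34 lower (8.59 expected, 5.18e-11). Taf5 and Taf13 MUT shared 3 higher (0.807 expected, exact adjusted p = 0.113) and 4 lower (2.31 expected, 0.402). The named genes were chosen after their values were seen. For the pairs in this order Pearson's r across genes was 0.2, 0.18 and 0.12 (Spearman's rho 0.21, 0.17 and 0.14). Genes are not independent. MUT averaged fewer genes above 0 than WT in each line, which was not separated from a shared response.

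Few genes differed between the lines when the effects were subtracted. The effect on Taf5 itself was lower in the Taf5 line than in the Taf12 line (log2 difference −7.42, SE 0.85, adjusted p = 5.71e-05) and the Taf13 line (−5.73, SE 0.87, adjusted p = 0.00888). Dynlt3, a dynein light chain (2.87, adjusted p = 0.00899), and Ezr, which links membrane and actin (4.33, adjusted p = 0.0479), had a higher effect in Taf5 than in Taf12, and Pcif1 in Taf5 than in Taf13 (2.68, adjusted p = 0.0137). Taf13 (2.31) and H1f2 (3.86) had a higher effect in Taf12 than in Taf13 (adjusted p = 0.0384 each), as had the clone 3830406C13Rik (4.35, 0.0384), named after its value was seen. Cholesterol synthesis (20 genes, median −1.04, adjusted p = 7.51e-06, adjusted p = 0.375 with an estimated correlation) and naive pluripotency genes (23 genes, −0.81, 2.73e-05, adjusted p = 0.23 with an estimated correlation) were lower in Taf12 than in Taf13. Naive pluripotency genes were higher in Taf5 than in Taf12 (23 genes, 0.81, 0.000611, adjusted p = 0.429 with an estimated correlation), with 0 members called over all genes in these 3 tests and 1, 3 and 4 adjusted over the list alone.

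The line contrasts called 3 (Taf5 against Taf12), 2 (Taf5 against Taf13) and 3 (Taf12 against Taf13) of 14446 genes. Under an unadjusted p of 0.05 were 1176, 922 and 1259 genes, and voom called 9, 11 and 5. The Taf5 calls and Dynlt3 held without each library. Ezr was lost without 12 of the 15 (highest 0.093, without Taf12 WT 4) and Pcif1 without Taf13 WT 2 alone (0.0506). Taf13 and H1f2 were lost without any of Taf12 WT 1, WT 3, WT 4, WT 5 or MUT 1, or of the 4 Taf13 WT (0.0522 to 0.083), and H1f2 without Taf12 MUT 2 (0.056) and Taf13 MUT 3 (0.0738).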

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

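The splits of the samples and the tests of explanations in this part were chosen after the results they measure were seen, while the differences between effects were fixed in advance.

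Epiblast genes were lower in Taf13 MUT at E6.5 (list median −3.23 on the log2 scale) while genes of the decidua and uterus were higher. More maternal tissue would lower all embryonic lineages alike. The visceral endoderm list had a median of 0.19 (bootstrap over genes, not embryos, −0.28 to 0.81, 2000 resamples). This argues against maternal tissue as the whole cause only if it lacks these transcripts. Missing epiblast cells and epiblast cells without their transcripts both predict few reads of Pou5f1. It had 0 over both MUT libraries, so these explanations cannot be told apart. An effect of the genotype stays open, untested beyond these 2 embryos.

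Taf13 transcript was higher in Taf12 MUT outgrowths. Its share of recovered reads, which the authors' scaling does not enter, was higher by log2 2.03 (205 to 297 per M in MUT, 54.2 to 76.6 in WT), which argues against that scaling. Without MUT 3, the library of lowest depth, its log2 fold change was 2.08, which argues against low depth of that library. A response of Taf13 to the Taf12 genotype is a hypothesis found on these same data. A changed mix of cells and reads shared with other transcripts were not tested and stay open.

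The genes called in Taf13 MUT blastocysts came from groups of unequal embryo sex by Ddx3y, read in 4 of 4 WT and 1 of 3 MUT. With the X and Y chromosomes left out 16 genes were called, which argues against calls from the sex chromosomes themselves. With the Ddx3y level as a covariate 0 were called, at adjusted p = 0.107 to 0.269 for the 16. Their median absolute log2 fold change was 3.48 before and 3.56 with the covariate, and their median SE rose from 0.46 to 0.58, so the calls ended through the wider error. Autosomal genes that differ with embryo sex and an effect of the genotype cannot be told apart, because only MUT 2, with Ddx3y, and HET 2, without it, part sex from genotype.

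Other splits of the same libraries were counted where each group held at least 3. Chance is unlikely for Taf12 MUT blastocysts (184 calls, 7 in the highest other split, 1 of 56 splits as high). So it is for outgrowths (4956 against 1, 1 of 35). Closer counts leave chance open for Taf13 MUT blastocysts (16 against 6) and, apart from Taf5 itself, Taf5 MUT (12 against 11). Both had 1 of 35, the minimum. For the Taf12 stage difference 2 of 100 drawn from 3920 were as high (1658 against 1903). The highest moved blastocysts only, so the count does not rest on their labels and chance stays open. Every split reaches a count of 0, so nothing was decided for Taf12 HET blastocysts (0 against 6, 100 of 100 drawn from 126), Taf13 HET blastocysts (0 against 5, 35 of 35) and Taf13 HET at E6.5 (0 against 3, 100 of 100 drawn from 715). Chance cannot be excluded for Taf12 HET outgrowths (4 against 6, 3 of 35). Nor can it for Taf5 against Taf12 (3 against 6, 8 of 100 drawn from 1960), Taf5 against Taf13 (2 against 4, 20 of 100 drawn from 1225) or Taf12 against Taf13 (3 against 20, 7 of 100 drawn from 1960). The split with 20 calls kept the Taf12 labels and exchanged Taf13 MUT 1 with WT 3. Taf13 MUT at E6.5 and its stage contrast, with 2 MUT libraries, were not split.

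These differences between effects passed limma's test, with the limits on chance above. In the Taf12 line 1658 genes differed between outgrowth and blastocyst, with Snap91 at 10.56, Adh1 at 9.87, Trpv5 at 8.4 and Slc6a14 at 8.35 on the log2 scale, and Cts7 at −9.51, Ceacam15 at −9.5, Tfpi2 at −7.88 and Tfr2 at −7.51. In the Taf13 line 722 differed between E6.5 and E3.5, with Osbpl5 at 6.76, Mthfd1l and Adck2 at 6.72 each and Wwox at 6.32. Tdgf1 was at −9.69, Pou5f1 at −8.57, Gng3 at −6.39 and Fgf8 at −6.38, and the list medians were −2.63 for postimplantation epiblast, −2.35 for anterior visceral endoderm and −1.41 for naive pluripotency. Between lines at E3.5, 3 genes differed for Taf5 against Taf12 (among them Ezr at 4.33, Dynlt3 at 2.87 and Taf5 at −7.42), 2 for Taf5 against Taf13 (Pcif1 at 2.68 and Taf5 at −5.73) and 3 for Taf12 against Taf13 (among them H1f2 at 3.86 and Taf13 at 2.31).

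Single libraries stood apart from their group in 38 of 554 groups of 4 to 10 values, where chance picks about 1 in 20. At E6.5, WT 3 had the highest Taf12 of its group (47.3 FPKM) and, as mean or gene log2(FPKM + 1), the highest decidua list (4.34), Lama1 (6.75), Des (4.65), Cdhr5 (3.14) and Dio3 (2.42), with the lowest Ccnd1 (6.97). HET 8 was highest for decidua (4.09) and apoptosis genes (4.88), HET 5 for parietal endoderm (5.99) and WT 2 for cholesterol synthesis (5.32). In Taf5 blastocysts, MUT 4 was highest for primitive endoderm (4.36), Bpgm (1.4), Lrrc75b (0.596) and Zmat3 (0.571), and MUT 1 for maternal and oocyte transcripts (6.59) and Btg2 (1.81). In Taf12 blastocysts, HET 1 was highest for blood and immune genes (5.86) and for Taf5 (53.4 FPKM), and WT 4 for Nlrp14 (2.56) and Bean1 (1.85). Apoptosis genes were lowest in HET 3 (4.94) and WT 2 (5.03), and glycolysis genes (4.73) and mt-Nd5 (12) in WT 3. Oxidative phosphorylation genes were highest in Taf13 blastocyst WT 2 (8.04).

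Among outgrowths, WT 2 had the fewest reads of its group (9.51 M), the highest parietal endoderm list (6.29) and the lowest Krt18 (9.63), and WT 4 had the lowest extraembryonic ectoderm list (5.68). Polr2a was lowest in WT 1 (8.14), and Trpv5 (5.02) and Adh1 (0.814) were highest in WT 3. Of the MUT libraries, MUT 2 was highest for Pxylp1 (0.589) and Apom (0.264), MUT 3 highest for Ret (4.6) and lowest for Polr2a (9.29), and MUT 4 lowest for Ncl (8.56).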

How the results depend on the processing

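The embryo-sex covariate, the filter on recovered reads, and leaving out X and Y or E6.5 WT 3 and HET 8 came after the results. The other alternatives were fixed in advance. Counts of calls, targeted transcripts and overlaps stayed on their side of the threshold with the same direction, or within 1.5 times of the count, in 468 of the comparisons with an alternative. Another 121 moved, 12 became weaker, 1 became stronger and 8 reversed. For named genes and gene groups, 11460 stayed, 957 became weaker, 71 stronger and 31 reversed. The rise of Taf12 in outgrowth MUT held under every alternative run, at log2 1.05 to 1.25. Causes not given here were not tested.

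Pseudocount and filter changed several small counts. With pseudocount 5, Taf5 MUT had 6 calls, the Taf5 transcript was at −2.87 and no longer called, Taf13 MUT blastocysts had 5 calls, the line contrasts 7, 1 and 6 (Taf5 against Taf12, Taf5 against Taf13, Taf12 against Taf13), and 1 gene was shared by Taf5 and Taf12. With pseudocount 0.1 Taf12 against Taf13 had 11. With no filter Taf5 MUT had 4, with its transcript at −4.99 but not called, Taf12 MUT blastocysts 67, Taf13 MUT blastocysts 8, Taf13 HET at E6.5 2 and Taf12 against Taf13 0. With the filter at FPKM 5 Taf5 MUT had 5, its transcript again at −4.99 and not called, HET outgrowths 1 and Taf12 against Taf13 7. Over all alternatives the adjusted p of the Taf5 transcript ran from 1.67e-05 (the authors' table) to 0.53 (replicate block).

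Scaling and the variance model left most counts within 1.5 times. Median-of-ratios, which moved the median of all genes by 0.02 or less, gave 5 calls for Taf12 against Taf13. Quantile normalization gave 5 for Taf5 against Taf12 and 6 for Taf12 against Taf13, and turned the uncalled values of Taf5 (−0.08) and Taf12 (−0.02) in Taf13 MUT at E6.5. It moved the median of all genes by 0.13 in Taf12 MUT blastocysts and by −0.16 in the Taf13 stage contrast. limma without trend or robust fitting gave 21 calls for Taf5 MUT and 5 for Taf5 against Taf12. Array weights gave 112 for Taf12 MUT blastocysts and 0 for Taf12 against Taf13. They also turned uncalled values of Taf13 in Taf12 HET blastocysts (−0.02), Taf13 in E6.5 MUT (0.1) and Taf12 in the Taf13 stage contrast (0.03). The 2-fold limit left 2913 calls in outgrowth MUT by construction.

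The count test voom called 0 genes in Taf5 MUT, with Taf5 at −7.41 and not called, 0 in HET outgrowths, 1 in Taf13 MUT blastocysts, and 9, 11 and 5 in the line contrasts in the order above. Fits of only the groups compared, which hold fewer samples, gave 41 for Taf12 MUT and 1 for HET blastocysts, 0 for HET outgrowths, 10 for Taf13 MUT and 2 for HET blastocysts, 474 at E6.5, 368 for the Taf13 stage contrast and 1 for Taf12 against Taf13. With WT and HET together as control, which holds more samples, the counts were 441 for Taf12 and 30 for Taf13 MUT blastocysts, 3348 at E6.5, 2522 and 1628 for the Taf12 and Taf13 stage contrasts, 5 for Taf5 against Taf12 and 26 for Taf12 against Taf13. At E6.5 Taf13 (0.14) and Taf5 (−0.18) turned, neither called. The authors' table listed 220 genes for Taf5 and 1294 for Taf12 MUT blastocysts, where Taf12 at 0.53 passed, 532 for Taf13 MUT blastocysts and 4108 at E6.5, with Taf13 at 0.09 and Taf5 at −0.15. Its overlaps were 55 (Taf5 and Taf12), 23 (Taf5 and Taf13) and 111 (Taf12 and Taf13). The overlaps of the limma fit at an unadjusted p under 0.01 were 38, 7 and 45 in the same order.

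With the Ddx3y covariate Taf5 MUT had 3 calls and Taf5 was at −4.65, not called. HET outgrowths had 2, Taf13 MUT blastocysts 0 and HET blastocysts 1, Taf12 against Taf13 had 1, and Taf13 in Taf12 HET blastocysts was at −0.03. With X and Y genes left out Taf5 against Taf12 had 1. Without E6.5 WT 3 and HET 8, Taf13 in E6.5 MUT was at 0.15 and Taf12 in the stage contrast at 0.06.

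The replicate numbers were also fitted as a block, though the labels do not say that they pair embryos. Libraries of the same number had a median correlation of residuals of −0.03, 0.007, −0.016, −0.015 and 0.025 in Taf5 blastocysts, Taf12 blastocysts, outgrowths, Taf13 blastocysts and E6.5. The block left 2, 6, 5, 5 and 4 residual degrees of freedom against 5, 10, 8, 8 and 12 without it. It gave 0 calls for Taf5 MUT (Taf5 at −4.99, not called), 48 for Taf12 MUT blastocysts, 0 for HET outgrowths, 0 for Taf13 MUT blastocysts and 584 at E6.5, where Taf13 was at 0.06. In E6.5 HET it turned Taf12 (−0.12), Rpl39 (−0.03), Rps28 (−0.02), Atp5k (−0.09) and Sdhc (−0.06), none called. It also turned the ribosomal (−0.26, adjusted p = 1.3e-08) and oxidative phosphorylation lists (−0.22, 0.0022), which passed in the other direction. It was not fitted for contrasts between stages or lines.

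Without 1 library at a time, calls ran from 3 to 10 in Taf5 MUT, 78 to 226 in Taf12 MUT and 0 to 1 in HET blastocysts, 0 to 7 in HET outgrowths, 9 to 26 in Taf13 MUT and 0 to 2 in HET blastocysts. They ran from 554 to 2066 at E6.5, 314 to 887 in the Taf13 stage contrast, and 2 to 17, 1 to 10 and 0 to 22 in the line contrasts. The Taf5 transcript ran from −5.58 to −4.63. Ranges that crossed 0 in E6.5 MUT were those of Taf13 (−0.2 to 0.15), Taf5 (−0.47 to 0.66) and Mvd (−2.75 to 0.1). In E6.5 HET they were those of Taf12 (−0.04 to 0.21), ribosomal (−0.04 to 0.34) and oxidative phosphorylation genes (−0.02 to 0.27). Others were Taf13 in Taf12 HET blastocysts (−0.07 to 0.13), Taf12 in HET outgrowths (−0.25 to 0.05), and Taf12 (−0.21 to 0.06) and extraembryonic ectoderm genes (−1.91 to 0.09) in the Taf13 stage contrast.

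Depth and group size limit what could be called. In outgrowth MUT 3, the library of lowest depth, 3 reads of Taf5 correspond to 2.62 FPKM, so low levels of such genes are uncertain there.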

Other observations

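The correlation test below was set before its result was seen.

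Other lineage groups of the Taf12 outgrowths did not pass as groups. As mean log2(FPKM + 1) ± SD, primitive streak and mesoderm genes were at 5.58 ± 0.52 in WT, 5.44 ± 0.5 in HET and 4.24 ± 0.5 in MUT (7 genes, 3 lower and 1 higher in MUT, adjusted p = 0.123). Extraembryonic ectoderm genes were at 6.17 ± 0.33, 5.78 ± 0.26 and 5.48 ± 0.11 (18 genes, 6 lower and 3 higher, adjusted p = 0.34), and anterior visceral endoderm genes at 3.63 ± 0.81, 2.76 ± 0.46 and 1.35 ± 0.98 (4 genes, 1 lower, adjusted p = 0.264). Maternal and oocyte transcripts were at 1.42 ± 0.48, 1.28 ± 0.36 and 3.17 ± 0.72 (5 genes, 2 higher and 1 lower, adjusted p = 0.338).

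Sex-linked transcripts varied between embryos of a group. Ddx3y, on the Y chromosome, was at 106, 108 and 105 FPKM in outgrowth MUT 1, MUT 3 and MUT 4 with 0 reads in MUT 2, and at 91.4 and 109.6 in WT 2 and WT 4. In Taf5 MUT it was read in MUT 3 alone (133 FPKM), and in Taf12 MUT blastocysts in MUT 1 alone (151 FPKM). Both E6.5 MUT libraries held Xist, which silences an X chromosome in females (8.43 and 1.82 FPKM), together with Ddx3y (2.01 and 1.04 FPKM), as did WT 1 among others (3.31 and 11.3 FPKM).

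A hypothesis is that Taf12 MUT outgrowths keep expression closer to the E3.5 blastocyst than WT outgrowths do. Over 11187 genes the MUT effect in outgrowths was correlated with the difference of blastocyst WT from outgrowth WT, with separate WT libraries on each side. Over the 6 ways to divide the outgrowth WT libraries Pearson's r averaged 0.31 and ran from 0.26 to 0.36 (Spearman's rho 0.23 on average), so the mean lies next to the bound of 0.3 set for the test and some divisions fall under it. The mean of 0.31 is consistent with MUT outgrowths that may hold on to part of the blastocyst pattern. The 2 stages were normalized separately by the authors, and a changed mix of cells would give a correlation as well.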
